A study of Homo sapiens with 172 samples.

How the data were processed

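RNA was sequenced from regulatory T cells (Treg) and memory T cells (Tmem) that had been sorted from blood and from mucosal biopsies of people with Crohn's disease (CD) or ulcerative colitis (UC), before and after treatment with vedolizumab. Per the labels' protocols, total RNA was prepared with a Qiagen miRNeasy Micro kit, and the indexed libraries were pooled in groups of 20 and read on 9 NextSeq500 flow cells. The 172 libraries fell into 12 groups by disease, time, tissue and cell type, as the labels give them, and biopsies were labelled before treatment only. The labels name no donors. Several libraries may come from 1 donor, the tests treated libraries as independent, and p-values may therefore be too small.

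The authors deposited 1 table of whole-number read counts per gene, not normalized, with a column for each library. The submitters' processing notes name STAR 2.5.0, HTSeq 0.11, DESeq2 1.22.2 and the build GRCh38. The roles and settings of these tools, the strandedness of the counting and the annotation were not given in the sources used here. The table held 58302 genes, of which 5594 had no count in any library, and it had no entry that names no gene. GENCODE release 29 on GRCh38 held 58039 of the gene IDs and gave the coordinates. In 27 entries a spreadsheet had turned the symbol into a date, and the symbol was taken from GENCODE by gene ID. Y-linked genes, the XIST region and alternative-haplotype copies (527 entries) were left out of every test and library size, and held at most 0.561% of a library. No pair of libraries within a group was a duplicate: over 1309 pairs, the chi-square per degree of freedom of genes with a summed count of at least 20 was never below 46.0.

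The libraries held 963525 to 55241291 gene counts. Depth, the number of genes with a count and the mitochondrial share were compared with 2-sided permutation tests of the log10 values (100000 resamples). Benjamini-Hochberg adjustment was over 12 planned tests of depth and detected genes and separately over the tests of mitochondrial share, which were added after the data were seen. A shallow library sees few of the low transcripts, and floors cover counting error only. Bootstrap intervals resampled the libraries (10000 draws) and cover the spread between them. The last digit of a sample label took 9 values with 16 to 20 libraries each. Its meaning is not stated, depth differed between digits, and it was used only as an alternative factor.

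Gene counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr by group, robust quasi-likelihood fits with glmQLFit and glmQLFTest). Only the libraries of the groups compared entered each fit, and disease was a covariate wherever both diseases entered together. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Where no gene differs, a share of about 0.05 of the genes tested is expected to have an unadjusted p under 0.05. Adjusted p-values are from edgeR unless another tool is named. Values are log2 fold changes ± standard error, the error being the absolute log2 fold change divided by the square root of the quasi-likelihood F. Levels are CPM, the counts scaled to a common library total, and log2 CPM levels used a prior count of 1. A fold against an arm with no count was set against a floor of 3 counts over the arm, and no fold is printed for a gene with 1 to 3 counts in an arm. The 14 gene comparisons were Treg against Tmem in biopsies and in blood, biopsy against blood in each cell type, after against before vedolizumab in each blood cell type, UC against CD in 4 arms, and 4 interaction terms.

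The choices of groups, tests, lists and named genes were made before the data were examined. The genes named were, in each comparison, the 8 with the largest rise and the 8 with the largest fall among those past the threshold with a mean log2 CPM of at least 3, up to 4 members of each list with the smallest p, and always FOXP3, IL2RA, CTLA4, ITGA4, ITGB7, CCR7, CD69, ITGAE and 1 further gene that is not reported here. The text takes examples from these. The 34 gene lists covered a Treg signature, a conventional T cell signature, tissue residency, recirculation, gut homing and integrins, Th1, Th17, Th2 and Tfh genes, checkpoint receptors, cytotoxic genes, TNF and NF-κB targets, the interferon response, immediate early genes, heat shock, proliferation, glycolysis and hypoxia, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, ribosomal proteins, MHC class II, AHR and retinoic acid, the TGF-β response, lipid and cholesterol genes and the glucocorticoid response. A further 9 of the 34 were markers of T cells, CD8 and γδ T cells, NK cells, B and plasma cells, myeloid cells, neutrophils and mast cells, epithelium, stroma and endothelium, and red cells and platelets. Lists held 6 to 50 genes and some genes stand in more than 1 list. Lists were tested with limma 3.58.1 on voom values: camera with a preset correlation of 0.01, camera with the correlation estimated, and fry, each adjusted over the lists of a comparison. The fry test asks whether the members of a list move one way on balance and does not compare the list with other genes.

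Alternatives were DESeq2 1.42.0, limma voom with sample quality weights, RLE scaling, no filter on low counts, 1 fit of all libraries, the label digit as a factor, log10 depth as a covariate, each disease alone, the shallowest library left out and, where a comparison before treatment had a counterpart, the libraries after treatment. A further filter was chosen after seeing the data and left out 20 libraries with fewer than 10000 or more than 30000 genes with a count or with over 40% mitochondrial counts. Each comparison was also refitted on other splits of its libraries into arms of the same sizes, and 3 comparisons were refitted without each library in turn.

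The procedure was tested on simulated data drawn from the real means, dispersions and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. Dispersions were estimated without the term under test, so real differences between the arms widened the simulated spread. Recovery may therefore be understated where many genes differ, as in biopsies. For biopsy Treg against Tmem edgeR recovered 40 of the 100 genes changed 2-fold and 82 of the 100 changed 4-fold, with 23 false calls, and for blood Treg against Tmem 49 and 87, with 14 false calls. For Treg after against before treatment it recovered 3 and 44 with 4 false calls. For the difference of the Treg contrast between biopsy and blood it made 152 false calls among 22987 unchanged genes, against 25 by DESeq2 and 7 by limma, so some of the edgeR calls of that comparison are false. Python 3.11.15 was used for tables and figures.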

Results

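RNA sequencing counts were available for 172 libraries of sorted T cells from people with Crohn's disease (CD) or ulcerative colitis (UC), the main forms of inflammatory bowel disease. Regulatory T cells (Treg), which carry the transcription factor FOXP3 and restrain immune responses, and memory T cells (Tmem) were sorted from blood and from mucosal biopsies. Vedolizumab is an antibody against the α4β7 integrin and limits the entry of lymphocytes into the gut. The study's stated purpose was to relate Treg transcription to the response to vedolizumab, but the labels used here name no responders, so response was not analysed. Before treatment the CD groups held 17 blood Tmem, 12 blood Treg, 20 biopsy Tmem and 12 biopsy Treg libraries, and the UC groups 14, 7, 27 and 8. After treatment there were 17 blood Tmem and 13 blood Treg libraries in CD and 14 and 11 in UC.

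Libraries held 963525 to 55241291 gene counts. The median was 19686014 counts in blood Tmem and 20041381 in blood Treg before treatment and 16560926 and 10717634 after it. Biopsy Tmem had a median of 17120083 counts and biopsy Treg one of 17713561. Blood Treg libraries after treatment had 0.438 times the counts of those before it (geometric means, 24 against 19 libraries, permutation test, p = 0.00016, adjusted p = 0.0019). No difference in depth passed in the other 5 comparisons tested (adjusted p from 0.25 to 0.69). Mitochondrial transcripts took 3.01% to 77.6% of a library's counts. Their share was 14.2% at the median in biopsy Treg and 8.70% in blood Treg before treatment (ratio of geometric means 1.47, permutation p = 0.034, adjusted p = 0.10). In blood Treg after against before treatment it had a ratio of 1.65 (permutation p = 0.034, adjusted p = 0.10), and the number of genes with a count one of 0.736 (permutation p = 0.014, adjusted p = 0.084).

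The comparison of Treg with Tmem in biopsies before treatment (20 against 47 libraries) asked which genes set mucosal Treg apart. Macrophage transcripts were higher in the libraries labelled Treg. FOLR2, a folate receptor of tissue macrophages (ENSG00000165457, chromosome 11, 72216601 to 72221950, GRCh38), was higher by a log2 fold change of 7.36 ± 0.66 (SE, adjusted p = 5.0e-14). CD163L1, a scavenger receptor of macrophages, was higher by 7.37 ± 0.90 and MS4A4A, a membrane protein of macrophages, by 7.05 ± 0.65. Each of these 3 genes lay above the Tmem median in 20 of 20 libraries. PLA2G2D, a secreted phospholipase, and F13A1, a coagulation factor chain that macrophages make, were higher by 7.85 ± 1.0 and 6.90 ± 0.81. C1QA and C1QB, which encode chains of the complement component C1q, were higher by 6.14 ± 0.59 and 6.30 ± 0.61, and CD74, the invariant chain of MHC class II, by 3.71 ± 0.31, with medians of 19850 against 1205 CPM. T cell transcripts fell. CD2, an adhesion receptor of T cells, had a log2 fold change of -2.20 ± 0.36 and lay below the Tmem median in 20 of 20 libraries. CD3E of the T cell receptor complex had -1.81 ± 0.37 and TRAC, the constant part of the receptor's α chain, -1.84 ± 0.34. FOXP3, the defining transcription factor of Treg (ENSG00000049768, chromosome X, 49250436 to 49264826), had medians of 5.28 CPM in the libraries labelled Treg and 25.1 CPM in Tmem and had counts in 13 of 20 and 47 of 47 libraries. Its log2 fold change of -1.0 ± 0.55 did not pass (adjusted p = 0.15).

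Counts of called list members showed the same separation in biopsies, though camera with an estimated correlation called 0 of the 34 lists. Of the myeloid markers 19 of 20 were higher (median log2 fold change 3.87, 19 adjusted over the list alone), among them FCER1G, the shared signalling chain of Fc receptors, at 4.11 ± 0.42. All 10 MHC class II genes were higher (median 3.83, 10 adjusted over the list alone), HLA-DRB1 by 3.99 ± 0.43. Stromal and endothelial markers were higher for 15 of 16 (16 adjusted over the list alone), with PECAM1, an adhesion molecule of endothelium and also of myeloid cells, at 3.80 ± 0.56. B and plasma cell markers were higher for 5 of 18 and epithelial markers for 8 of 25 (5 and 10 adjusted over the list alone). T cell markers were lower for 11 of 12 and higher for CD4 (1.11 ± 0.19), a co-receptor that macrophages also carry (11 lower and 1 higher adjusted over the list alone). The conventional T cell signature was lower for 16 of 17 genes (16 adjusted over the list alone). Among them were IL7R, the interleukin 7 receptor, at -2.22 ± 0.36, CD40LG, the CD40 ligand of helper T cells, at -2.78 ± 0.49 and THEMIS, a T cell signalling protein, at -2.58 ± 0.44. Th1 genes were lower for 9 of 13, Th17 genes for 9 of 15, Tfh genes for 7 of 12 and cytotoxic genes for 8 of 15 (11, 10, 8 and 11 adjusted over the list alone). Examples were STAT4, a Th1 transcription factor, at -1.76 ± 0.25, RORA, a Th17 transcription factor, at -2.01 ± 0.34, GZMK, a granzyme, at -4.50 ± 0.99, and CXCR3, a chemokine receptor of Th1 cells, at -2.63 ± 0.50. T cell markers fell as well. The falls of these lists and of the conventional T cell signature cannot be told apart from less T cell RNA in the libraries. The chemokine CCL4, which stands among the cytotoxic genes, was higher by 3.96 ± 0.37. Markers of CD8 and γδ T cells were lower for 2 of 6 (2 adjusted over the list alone). Lipid and cholesterol genes were higher for 7 of 16 and lower for 1, and glycolysis and hypoxia genes higher for 8 of 25 and lower for 4 (7, 2, 9 and 5 adjusted over the list alone).

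The Treg signature was mixed in biopsies, with 5 of 34 genes higher and 9 lower (6 and 10 adjusted over the list alone). EBI3, a subunit of interleukin 35 that myeloid cells also make, was higher by 3.59 ± 0.52. CTLA4, an inhibitory receptor, and BATF, a transcription factor of tissue T cells, were lower at -1.27 ± 0.49 (adjusted p = 0.035) and -1.51 ± 0.34. IL2RA, the interleukin 2 receptor α chain, had -0.10 ± 0.21 (adjusted p = 0.76) and turned sign with RLE scaling. Immediate early genes were higher for 16 of 24 and heat shock genes for 8 of 15 (18 and 8 adjusted over the list alone), IER3 by 2.65 ± 0.24 and the cochaperone BAG3 by 1.98 ± 0.20. The chemokine CXCL8, a TNF and NF-κB target, was higher by 4.52 ± 0.53, while that list had 8 of 23 higher and 8 lower (9 and 8 adjusted over the list alone). Ribosomal protein genes were lower for 48 of 50 (49 adjusted over the list alone), RPS27 by -1.15 ± 0.16. Of the integrins, ITGB7, the β7 chain that vedolizumab's target contains (ENSG00000139626, chromosome 12, 53191318 to 53207307), was higher by 1.19 ± 0.34 (adjusted p = 0.0047). ITGA4, the α4 chain (ENSG00000115232, chromosome 2, 181457202 to 181536187), was lower at -0.67 ± 0.14. CD69, a retention receptor of resident T cells, was lower at -1.86 ± 0.29 and CCR7, a lymph node homing receptor, at -0.85 ± 0.30. Because T cell markers fell too, lower values of T cell genes here cannot be told apart from less T cell RNA. Myeloid and stromal markers rose, so higher values, that of ITGB7 among them, cannot be assigned to Treg. ITGAE, the αE integrin of resident T cells, had -0.16 ± 0.30 and did not pass.

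In all, 6891 of 20378 genes passed in biopsies, 3927 higher and 2964 lower. Limma with quality weights put the balance the other way, with 4633 higher and 5346 lower. RLE scaling shifted the median of all genes by 0.13 and gave 4466 higher and 2348 lower. With the preset correlation camera called 18 of the 34 lists and with an estimated correlation none. The lowest adjusted p with an estimated correlation was 0.18, for the conventional T cell signature, the T cell markers and the myeloid markers. It was 0.27 for stromal markers, ribosomal proteins and immediate early genes, 0.34 for heat shock and 0.36 for MHC class II, Th1 and Th17 genes. Cytotoxic genes had 0.37, B and plasma cells 0.39, epithelium 0.41 and Tfh genes 0.48. Called by fry were 24 lists.

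**Figure D1:**
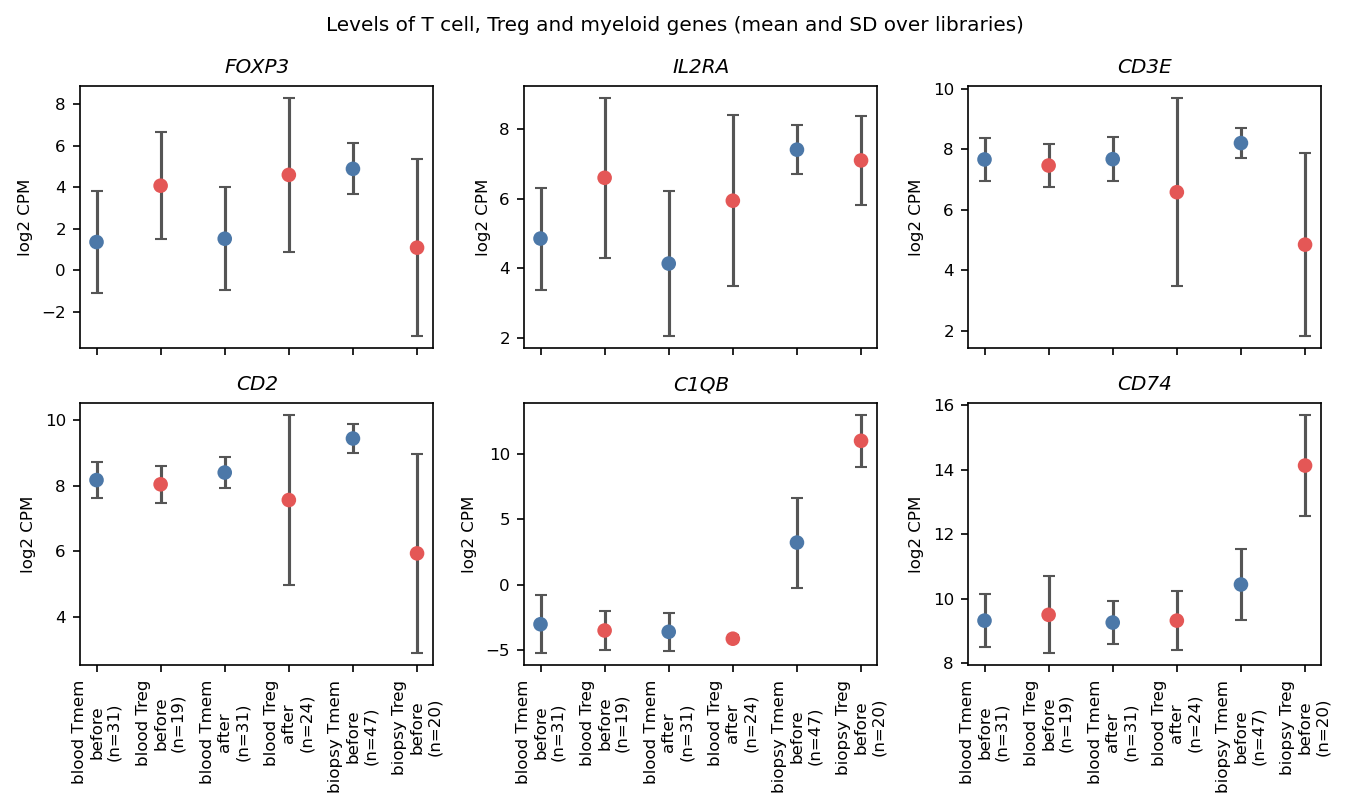
Mean log2 CPM (points) and SD over libraries (bars) of 6 genes in the 6 arms of cell type, tissue and time, with the number of libraries on the horizontal axis. In blood the means of FOXP3 and IL2RA were higher in Treg than in Tmem before and after treatment, with IL2RA after treatment short of the threshold (adjusted p = 0.092), and in biopsies the libraries labelled Treg had higher C1QB and CD74 and lower CD2 and CD3E than Tmem.

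In blood before treatment, Treg (19 libraries) differed from Tmem (31 libraries) in 14 of 18062 genes, 9 higher and 5 lower, with genes of Treg identity foremost. FOXP3 was higher in Treg by 2.98 ± 0.53 (adjusted p = 0.0038, above the Tmem median in 17 of 19 libraries) and IL2RA (ENSG00000134460, chromosome 10, 6010689 to 6062370) by 2.07 ± 0.36 (adjusted p = 0.0028). IKZF2, the Treg transcription factor Helios, was higher by 2.76 ± 0.58 and RTKN2, a Treg-enriched gene, by 2.34 ± 0.45. SGMS1, a sphingomyelin synthase (1.41 ± 0.24), STAM, an endosomal sorting adaptor (1.10 ± 0.22), and ANTXR2, an anthrax toxin receptor (1.5 ± 0.33), were higher as well. IFIT2 and OASL, which interferon induces, were lower at -2.19 ± 0.48 and -1.86 ± 0.39 and lay below the Tmem median in 19 of 19 libraries. The remaining 5 genes fell outside the naming rule and were picked after their values were seen: DPYS at 4.81 ± 0.92, IL1A at 4.75 ± 1.03, PRSS35 at -5.94 ± 1.23, SPTLC3 at -6.52 ± 1.29 and AL606760.3 at -6.29 ± 1.18, all with a mean level below 1 log2 CPM.

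Among the lists, the Treg signature had 4 of 33 members higher and none lower, and 14 higher adjusted over the list alone (camera, adjusted p = 8.6e-23, and adjusted p = 0.00032 with an estimated correlation). The interferon response had 2 of 34 lower, and 6 adjusted over the list alone (camera, adjusted p = 0.00028, and adjusted p = 0.31 with an estimated correlation), ISG15 among the latter at -1.67 ± 0.40 (adjusted p = 0.090 over all genes). No member of the checkpoint list passed over all genes, and 3 were higher adjusted over the list alone. LAYN, a C-type lectin of activated Treg, had 3.49 ± 0.84 (adjusted p = 0.094), TIGIT, a checkpoint receptor, 1.0 ± 0.32, CTLA4 1.17 ± 0.41 (adjusted p = 0.56), CXCR3 -1.07 ± 0.30 and the chemokine CCL5 -1.53 ± 0.52. ITGA4 at -0.29 ± 0.18 did not pass. Camera called 12 lists with the preset correlation. The 1 list called with an estimated correlation and the 1 called by fry was the Treg signature.

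The same contrast in the separate libraries after treatment (24 Treg, 31 Tmem) called 8 genes. Of the 9 genes called before treatment that could be tested after it, 9 kept their sign. FOXP3 was higher by 3.92 ± 0.54 (adjusted p = 6.1e-06), IKZF2 by 2.92 ± 0.57 and SGMS1 by 2.07 ± 0.43. These 3 passed both before and after treatment, where independent lists of the same size would share 0.0032 genes. The labels name no donors, so donors may be shared between the times and the lists may not be independent. Called after treatment were also LAYN (4.28 ± 0.95), TNFRSF9, the costimulatory receptor 4-1BB (3.57 ± 0.69), TTN (2.19 ± 0.35) and CEP170B (4.76 ± 0.92) and, as lower, CCL5 (-2.72 ± 0.48). CEP170B stood on the other side of 0 before treatment, at -2.59 (adjusted p = 0.51). With either disease alone no gene passed in the libraries before treatment. Refits without each library in turn called 10 to 19 genes, and FOXP3, IL2RA, RTKN2, SGMS1, STAM and AL606760.3 passed in 50 of 50 refits. IFIT2 passed in only 23, ANTXR2 in 37 and IL1A in 41 of them. The remaining genes passed in 45 to 49.

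**Figure D2:**
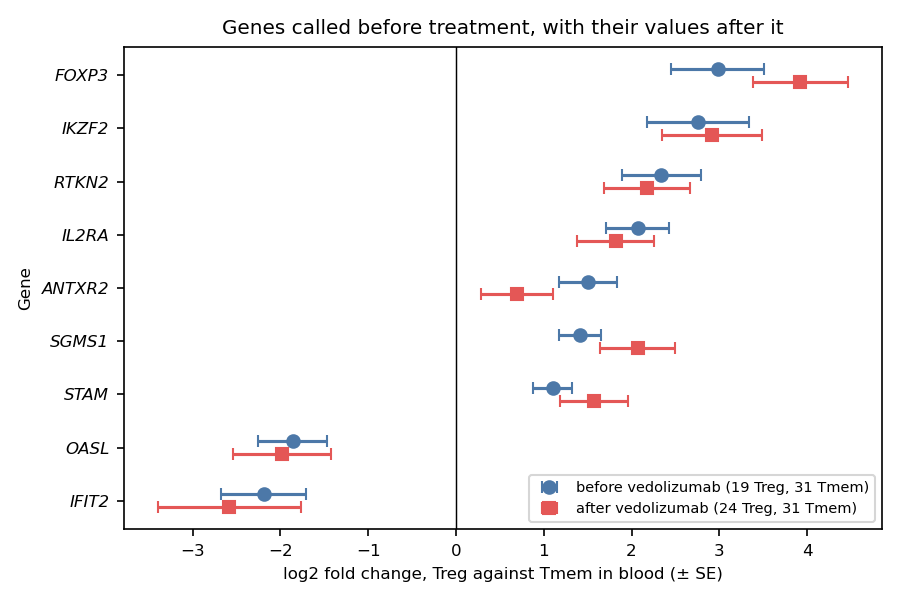
Log2 fold changes (points, bars are SE) of Treg against Tmem in blood for the 9 genes called before treatment that could be tested after it. All 9 lie on the same side of 0 before and after treatment, FOXP3 at 2.98 and 3.92.

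Biopsy Tmem (47 libraries) were compared with blood Tmem (31 libraries) before treatment to find what distinguishes memory T cells of the mucosa. Cells from biopsies and from blood were obtained in different ways, and effects of tissue and of preparation cannot be told apart in this comparison. Genes of egress from tissue fell. S1PR1, the sphingosine 1-phosphate receptor that guides exit from tissue (ENSG00000170989, chromosome 1, 101236865 to 101243713), had a log2 fold change of -3.62 ± 0.39 (adjusted p = 6.7e-12), with medians of 39.1 CPM in biopsies and 881.4 CPM in blood. The related S1PR5 had -5.10 ± 0.74, and KLF2 and KLF3, transcription factors of circulating T cells, had -2.73 ± 0.29 and -2.34 ± 0.16. Residency genes were higher, ITGA1, the α1 integrin, by 5.75 ± 0.53, ITGAE by 1.45 ± 0.26 and CD69 by 1.24 ± 0.22. IL17A, the cytokine of Th17 cells (ENSG00000112115, chromosome 6, 52186375 to 52190638), was higher by 7.57 ± 0.77, with counts in 41 of 47 biopsy and 4 of 31 blood libraries. AHR, a ligand-activated transcription factor, was higher by 2.48 ± 0.17. Genes of Treg and activated cells were also higher, FOXP3 by 2.93 ± 0.37, IL2RA by 2.21 ± 0.22, BATF by 2.46 ± 0.21, TNFRSF9 by 3.68 ± 0.42, TIGIT by 2.72 ± 0.29 and CTLA4 by 1.94 ± 0.33. The median of FOXP3 per 100 CPM of CD3D, CD3E, CD3G and CD2 was 1.70 in biopsy Tmem and 0.478 in blood Tmem. Whether the biopsy Tmem fraction held more Treg was not tested.

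By list, recirculation genes were lower for 9 of 14 and higher for none (10 lower adjusted over the list alone), including CCR7 at -0.78 ± 0.23 (adjusted p = 0.0061). The Treg signature was higher for 22 of 34 and lower for 1 (25 and 1 adjusted over the list alone). Th17 genes were higher for 10 of 15, checkpoint receptors for 11 of 14 and heat shock genes for 15 of 15 (10, 12 and 15 adjusted over the list alone). These 5 lists kept their camera call with an estimated correlation (adjusted p = 0.0031 for recirculation, 0.017 for the Treg signature, 0.011 for Th17, 0.019 for checkpoint and 0.011 for heat shock). IL1R1, the interleukin 1 receptor, was higher by 4.76 ± 0.47, LAG3, a checkpoint receptor, by 2.25 ± 0.31, and the chaperones HSPA1A and HSP90AB1 by 4.38 ± 0.36 and 1.49 ± 0.12. Tissue residency had 11 of 20 higher and 2 lower (11 and 2 adjusted over the list alone, adjusted p = 0.087 with an estimated correlation). Th1 genes were higher for 8 of 13, with IFNG, interferon γ, at 2.28 ± 0.46, and Th2 genes for 5 of 8 (8 and 5 adjusted over the list alone, adjusted p = 0.46 and 0.099 with an estimated correlation). IL2, the T cell growth factor, was higher by 6.20 ± 0.61. Gut homing and integrin genes went both ways, ITGA4 up by 0.61 ± 0.12 and the chemokine receptor CXCR4 down at -1.56 ± 0.15, with 6 of 16 higher and 4 lower (6 and 4 adjusted over the list alone).

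Among other groups in Tmem, immediate early genes also split, with FOSB at 3.16 ± 0.36 and FOSL2 at -1.76 ± 0.17. Of these 24 genes 13 were higher and 7 lower (14 and 7 adjusted over the list alone, adjusted p = 0.61 with an estimated correlation). So did the TGF-β response, with 4 of 13 higher and 5 lower (4 and 5 adjusted over the list alone), LDLRAD4 at 2.16 ± 0.18 and SMAD7, an inhibitor of TGF-β signalling, at -2.26 ± 0.20. Nuclear oxidative phosphorylation genes were lower for 14 of 27 and ribosomal proteins for 49 of 50 (15 and 50 adjusted over the list alone, adjusted p = 0.40 and 0.057 with an estimated correlation), with COX4I1 at -1.06 ± 0.11 and RPL14 at -1.25 ± 0.13. The glucocorticoid response had 4 of 13 higher and 5 lower and NK cell markers 1 of 6 higher and 2 lower (4, 5, 2 and 2 adjusted over the list alone). FGFBP2, a gene of cytotoxic lymphocytes, was lower at -7.68 ± 0.90, within a cytotoxic list of 2 of 16 higher and 6 lower (3 and 7 adjusted over the list alone). Also lower were WNT7A at -4.63 ± 0.56, EPHA4 at -3.02 ± 0.40 and RNF125, a ubiquitin ligase, at -3.13 ± 0.25.

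Markers of other cells were higher in biopsy Tmem alongside these groups. TPSAB1 and CPA3, mast cell proteases, were higher by 12.58 ± 0.98 and 12.93 ± 1.05, with medians of 45.1 and 29.0 CPM in biopsies against 0 in blood. The chemokine CXCL14 was higher by 11.33 ± 1.03, JCHAIN of plasma cells by 7.40 ± 0.93, C1QC of macrophages by 8.72 ± 0.78 and HLA-DRA of MHC class II by 2.68 ± 0.47. Epithelial markers were higher for 22 of 23, stromal and endothelial markers for 12 of 14, B and plasma cell markers for 11 of 16, neutrophil and mast cell markers for 6 of 8 and MHC class II for 10 of 10 (23, 13, 13, 6 and 10 adjusted over the list alone, adjusted p = 0.063, 0.087, 0.076, 0.057 and 0.36 with an estimated correlation). Myeloid markers were mixed, 7 of 19 higher and 3 lower (8 and 3 adjusted over the list alone), S100A8, a calprotectin subunit of neutrophils and monocytes, being lower at -3.19 ± 0.70. Red cell and platelet markers were lower for 3 of 7 (3 adjusted over the list alone), the platelet gene PPBP at -7.26 ± 0.80. In total 4982 of 18197 genes passed, 2787 higher (55.9%) and 2195 lower. RLE scaling shifted the median of all genes by 0.11 and put 66.0% of the calls on the higher side.

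In the libraries labelled Treg, biopsy (20) against blood (19) before treatment differed in 7196 of 18646 genes, 4467 higher and 2729 lower (5619 and 5346 with limma and quality weights, 4779 and 2449 with RLE scaling). Macrophage and tissue transcripts rose, SLCO2B1, a transporter of macrophages, by 14.99 ± 0.65, C1QC by 14.69 ± 0.67, the chemokine CCL24 by 14.92 ± 0.97 and ADAMDEC1, a protease of gut macrophages, by 15.08 ± 0.82. Their medians were 0 CPM in blood and 369.6, 540.2, 337.0 and 799.2 CPM in biopsies. Recirculation genes were lower for 7 of 14 and higher for 2 (9 and 2 adjusted over the list alone, adjusted p = 0.15 with an estimated correlation). S1PR1 stood at -4.47 ± 0.47, CCR7 at -1.44 ± 0.30, KLF3 at -2.10 ± 0.18 and CXCR4 of the homing list at -2.69 ± 0.31. ITGAE was higher by 1.64 ± 0.38 and ITGB7 by 0.88 ± 0.33 (adjusted p = 0.031). Markers of other cells rose as well, so these rises cannot be assigned to Treg. FOXP3 had -1.01 ± 0.86 (adjusted p = 0.37) and CTLA4 -0.64 ± 0.73, and neither passed, while RTKN2 fell by 4.08 ± 0.70. T cell markers fell too, so lower values of T cell genes in this comparison cannot be told apart from less T cell RNA.

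Heat shock genes were higher for 15 of 15 and immediate early genes for 17 of 24 (15 and 17 adjusted over the list alone, adjusted p = 0.14 and 0.22 with an estimated correlation). Examples were HSPA1A, higher by 4.92 ± 0.34, HSPB1 by 4.54 ± 0.31 and EGR1, an immediate early transcription factor, by 4.90 ± 0.57. As in Tmem, effects of tissue and of preparation cannot be told apart here. MHC class II rose for 10 of 10 (10 adjusted over the list alone), HLA-DQA1 by 7.03 ± 0.78 and CD74 by 4.61 ± 0.50. Myeloid markers rose for 14 of 20, epithelial for 24 of 25, stromal and endothelial for 15 of 15, B and plasma cell for 15 of 18 and neutrophil and mast cell markers for 6 of 9 (14, 25, 15, 16 and 6 adjusted over the list alone). The median of the epithelial list, 10.74, was 10.30 with its 12 members of 3 or fewer counts in an arm set at the floor. T cell markers fell for 7 of 12 and rose for 1, CD4 at 1.65 ± 0.23 (8 and 1 adjusted over the list alone). CD5 stood at -2.72 ± 0.64 and CD247, the ζ chain of the T cell receptor complex, at -2.51 ± 0.57. Mitochondrially encoded genes rose for 11 of 13 (12 adjusted over the list alone), MT-CO1 by 1.63 ± 0.25. Ribosomal proteins fell for 49 of 50 and the conventional T cell signature for 9 of 18, NELL2 at -4.73 ± 0.97 (49 and 10 lower adjusted over the list alone). Proliferation genes were higher for 11 of 26 (11 adjusted over the list alone) and Th17 genes for 9 of 14 with 3 lower (9 and 3 adjusted over the list alone), AHR at 2.11 ± 0.23, and TNF was higher by 2.75 ± 0.41. WNT7A and S1PR4, another sphingosine 1-phosphate receptor, fell by 7.69 ± 1.04 and 3.40 ± 0.61. With an estimated correlation none of the 16 lists called by camera passed. The lowest adjusted p with an estimated correlation was 0.14 for heat shock and the highest among those named here 0.58 for MHC class II and proliferation, and fry called 25 lists.

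Of the genes tested in both cell types, 1686 were higher in biopsies for both Tmem and Treg labels, where independent lists would share 553, and 1383 were lower for both, where independent lists would share 340. Opposite calls numbered 30 and 32. The contrasts share no libraries, but donors are not named and may be shared, so the lists may not be independent. T cell genes among the shared lower calls cannot be told apart from less T cell RNA in the biopsy libraries labelled Treg.

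**Figure D3:**
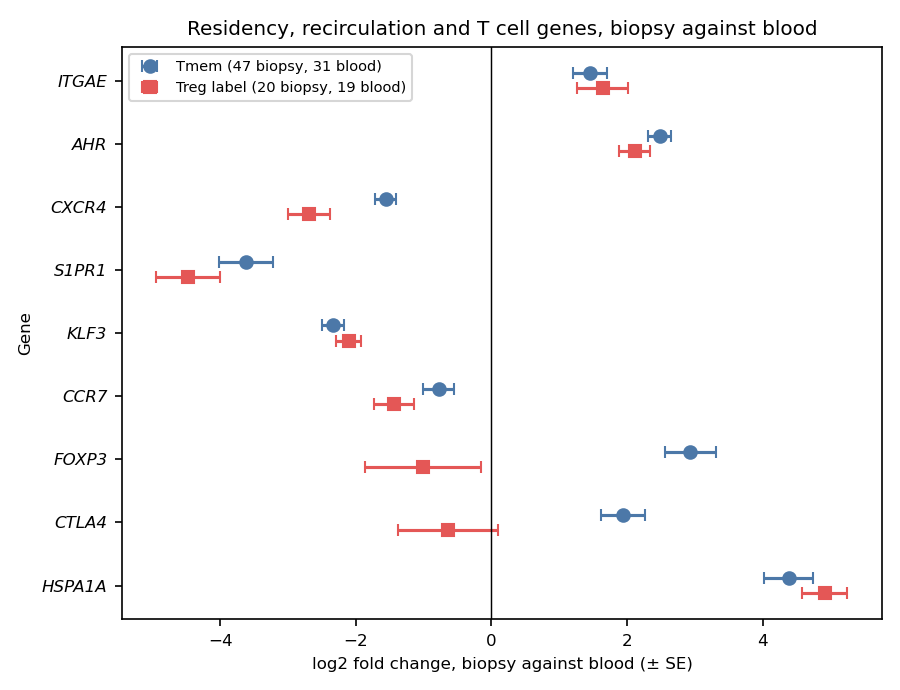
Log2 fold changes (points, bars are SE) of biopsy against blood before treatment for residency, recirculation, Treg and heat shock genes, in Tmem and in the libraries labelled Treg. S1PR1, KLF3, CCR7 and CXCR4 lie below 0 and ITGAE, AHR and HSPA1A above 0 in both, while FOXP3 lies at 2.93 in Tmem and at -1.01 in the libraries labelled Treg. Under the Treg label, lower values of T cell genes cannot be told apart from less T cell RNA.

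The difference between these contrasts was tested directly in the 117 libraries before treatment, as Treg against Tmem in biopsies minus the same in blood. The Treg genes FOXP3 (-3.98 ± 0.80, adjusted p = 0.00016), IKZF2 (-4.20 ± 0.87), RTKN2 (-4.59 ± 0.77), LAYN (-4.15 ± 0.97), CTLA4 (-2.48 ± 0.67) and IL2RA (-2.12 ± 0.42) had a lower contrast in biopsies than in blood. So did the T cell genes CD2 (-2.06 ± 0.38) and TRAC (-2.14 ± 0.37) and the mast cell gene CPA3 (-3.82 ± 1.24, adjusted p = 0.024), which turned to 1.20 with limma and quality weights. C1QB (8.14 ± 1.15), CD74 (3.22 ± 0.46) and COL3A1, a collagen of fibroblasts (8.74 ± 1.76), had a higher one. The Treg signature was lower for 16 of 34 and T cell markers for 10 of 12 with 1 higher (19, 10 and 1 adjusted over the list alone, adjusted p = 0.17 and 0.0027 with an estimated correlation). The lower contrast of Treg genes was not tested apart from less T cell RNA in the biopsy libraries labelled Treg. Myeloid markers were higher for 10 of 20 (12 adjusted over the list alone, adjusted p = 0.23 with an estimated correlation). In total 3549 of 23187 genes passed, 2118 higher (59.7%) and 1431 lower. RLE scaling shifted the median by 0.19 and put 71.1% on the higher side, and the simulation of this term gave 152 false calls with edgeR.

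**Figure D4:**
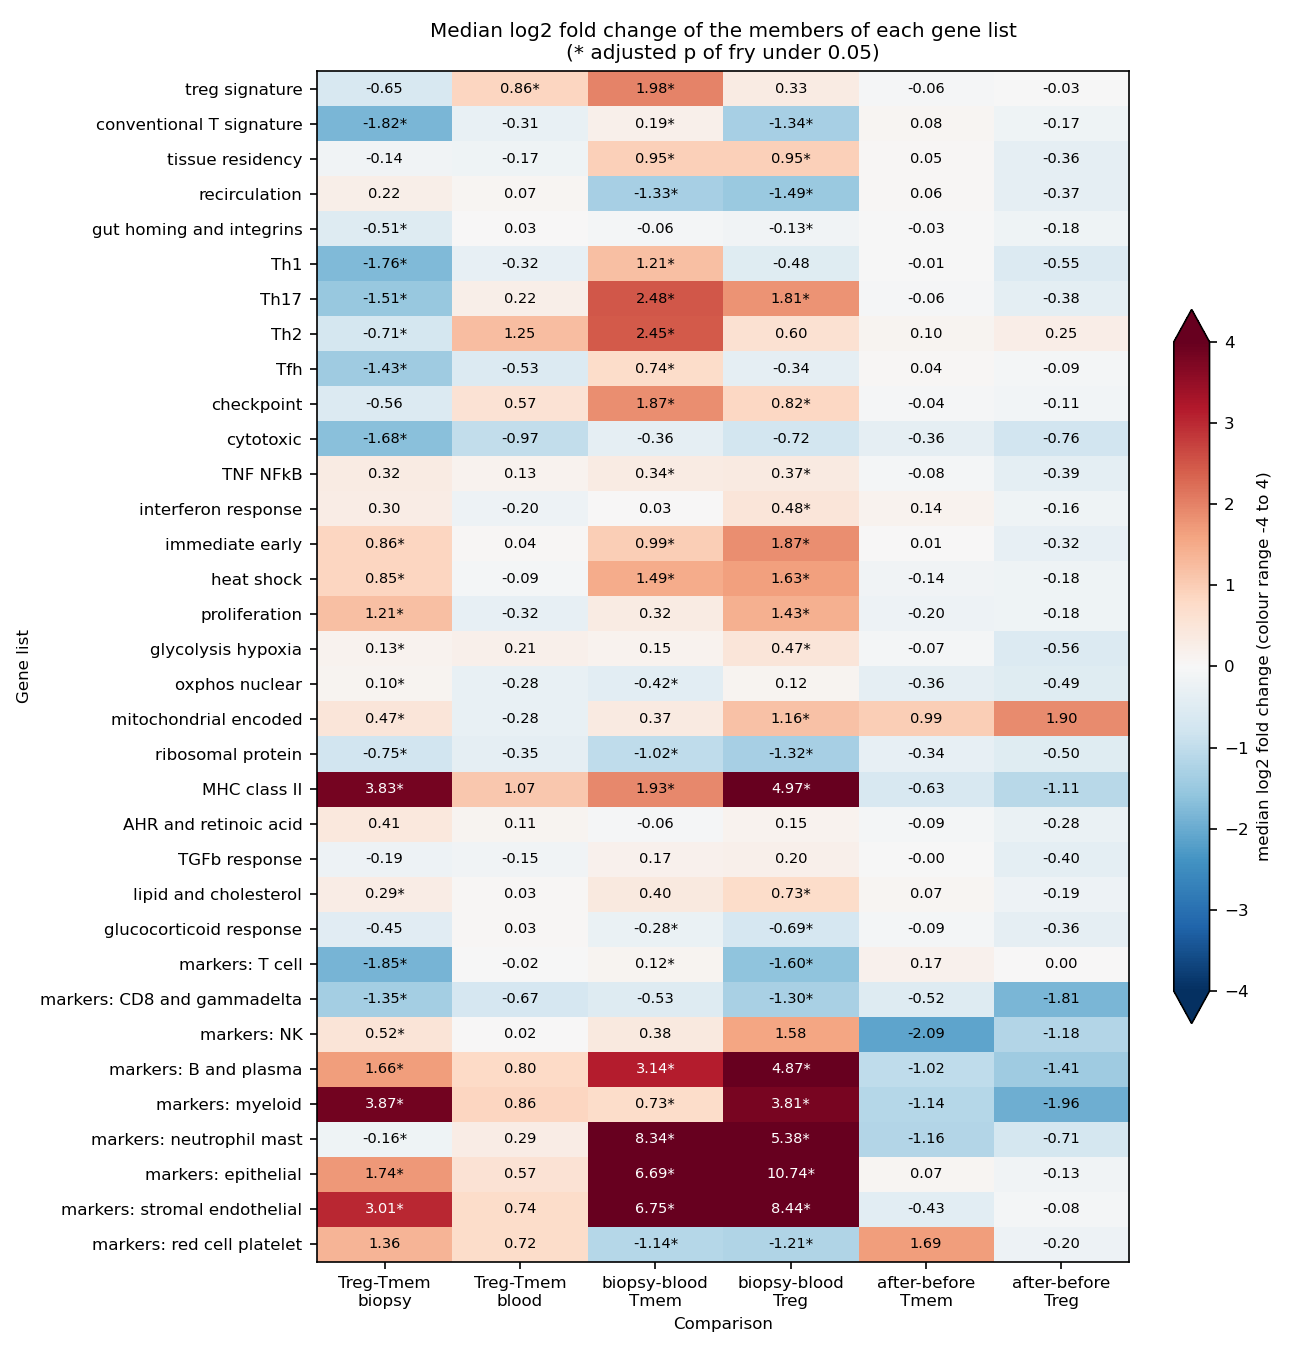
Median log2 fold change of the members of each of the 34 gene lists (numbers and colours) in 6 comparisons, with a star where the adjusted p of fry was under 0.05. Myeloid markers stand at 3.87 and T cell markers at -1.85 in biopsy Treg against Tmem, and the Treg signature stands at 0.86 in blood Treg against Tmem.

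After vedolizumab, blood Tmem (31 against 31 libraries) showed no gene past the threshold among 16089 tested with edgeR. An unadjusted p under 0.05 was reached by 1070 genes, and DESeq2 called 23 and limma with quality weights 0. The target chains had log2 fold changes of 0.36 ± 0.16 for ITGA4 (adjusted p = 0.70, above the median before treatment in 23 of 31 libraries) and 0.09 ± 0.33 for ITGB7. CD69 had -0.36 ± 0.23 and ITGAE -0.43 ± 0.35. Members with the smallest p in their lists included CCL2, a chemokine that attracts monocytes (-3.60 ± 0.91, adjusted p = 0.49), DHRS9, a retinol dehydrogenase (-3.58 ± 0.94), HLA-DRA (-1.33 ± 0.38), FCGR3A, the Fc receptor CD16 (-2.55 ± 0.84), DNAJA1 (-0.56 ± 0.18), COX7B (-0.57 ± 0.18) and RPL7 (-0.55 ± 0.16). Of the 13 mitochondrially encoded genes none passed over all genes with edgeR, 8 passed with DESeq2, and 13 were higher adjusted over the list alone, with MT-CO1 at 1.06 ± 0.27. Their median was 0.99 (camera, adjusted p = 6.0e-06, and adjusted p = 0.54 with an estimated correlation). The median fell to 0.17 with quality weights, and was 1.32 in CD alone and 0.46 (median SE 0.39) in UC alone, where 0 passed adjusted over the list alone. T cell markers kept a camera call with an estimated correlation (median 0.17, adjusted p = 0.027) though no member passed, and fry called no list. The counts of the mitochondrial genes went with a mitochondrial share of 9.75% at the median after and 9.58% before treatment (permutation p = 0.11, adjusted p = 0.17).

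After vedolizumab, blood Treg (24 against 19 libraries) differed in 28 of 16341 genes, 19 higher and 9 lower. Among the genes that fell, CCL2 (ENSG00000108691, chromosome 17, 34255218 to 34257203) stood at -5.28 ± 1.13 (adjusted p = 0.021), with counts in 5 of 24 libraries after and 10 of 19 before treatment. Lower too were DHRS9 at -5.09 ± 1.14, MMP19, a matrix metalloproteinase, at -5.69 ± 1.28, FAM49A at -5.07 ± 1.13 and IGKC, an immunoglobulin light chain of plasma cells, at -6.35 ± 1.16. Picked after their values were seen, the chemokines CCL7 and CXCL10 fell by 9.28 ± 1.51 and 5.13 ± 1.12. Higher were CEP170B (6.41 ± 1.47), the calcium channel gene CACNA1A (6.38 ± 1.16), PRRG3 (4.14 ± 0.78), SOCS7 (3.00 ± 0.70) and the mitochondrial gene MT-ATP8 (2.04 ± 0.45, adjusted p = 0.027). FOXP3 had 1.08 ± 0.60 (adjusted p = 0.66), IL2RA -0.78 ± 0.45, CCR7 -0.46 ± 0.27, ITGA4 -0.08 ± 0.32 and ITGB7 -0.42 ± 0.50, and none of these passed.

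Mitochondrially encoded genes were higher for 1 of 13 over all genes and for 13 adjusted over the list alone, with MT-CO1 at 1.76 ± 0.43. Their median was 1.90 (camera, adjusted p = 4.4e-12, and adjusted p = 1.0 with an estimated correlation). It was 2.34 with RLE scaling and with DESeq2, each with 13 passing over all genes, and fell to 0.24 with quality weights. It was 2.67 in CD alone and 1.18 (median SE 0.59) in UC alone, where 0 passed adjusted over the list alone. Ribosomal proteins were lower for 0 of 50 over all genes and for 19 adjusted over the list alone (RPL3 -0.88 ± 0.23). TNF and NF-κB targets were lower for 1 of 23 (2 adjusted over the list alone), with IL1B, interleukin 1β, at -5.10 ± 1.38 (adjusted p = 0.13), and myeloid markers for 0 of 15 (0 adjusted over the list alone), with a median of -1.96 and LYZ, lysozyme, at -2.33 ± 0.82. AHR and retinoic acid genes were lower for 1 of 12 and B and plasma cell markers for 1 of 8 (2 and 1 adjusted over the list alone). The 28 calls became 0 with log10 depth as a covariate, 1 with the label digit as a factor and 1 with the filter on few or very many detected genes or over 40% mitochondrial counts, which left out 8 of the 24 libraries after treatment and 0 of the 19 before it. Leaving out each library in turn gave 5 to 58 calls, with 12 of 43 refits more than 1.5 times away. RLE scaling shifted the median by 0.25 and called 82 genes, 87.8% of them higher, against 67.9% here.

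The change after treatment differed between Treg and Tmem in 194 of 20914 genes by edgeR, 160 higher in Treg and 34 lower. The balance turned with log10 depth as a covariate (34 higher, 81 lower), with the label digit as a factor (7 higher, 8 lower) and with the filter on libraries, which left 90 of 105 (3 higher, 24 lower). DESeq2 called 5 and limma with quality weights 0, and 30 of 60 splits of the same libraries called as many with edgeR. The simulation of this term gave 82 false calls with edgeR. None of the 34 lists was called by camera or fry. Of list members, the epithelial transcription factor ELF3 (7.41 ± 1.74, adjusted p = 0.015) and COL3A1 (6.29 ± 1.55) passed, and with the filter on libraries ELF3 stood at -2.02 and 27 genes passed. RLE scaling shifted the median by 0.13. Between UC and CD no gene passed for a difference in the change after treatment, among 16089 in Tmem (1000 with an unadjusted p under 0.05, DESeq2 0, limma 0) or 16341 in Treg (637, DESeq2 2, limma 0). Members with the smallest p in their lists included S100A8 in Tmem (-5.03 ± 1.54) and JUND, an immediate early gene, in Treg (-2.79 ± 0.71). Camera called 3 and 5 lists with the preset and 0 with an estimated correlation (adjusted p of at least 0.82 and 0.91).

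UC was compared with CD in each cell fraction before treatment. In biopsy Tmem (27 UC against 20 CD) 1 of 15092 genes passed: NCOA3, a nuclear receptor coactivator (ENSG00000124151, chromosome 20, 47501902 to 47656877), was lower in UC at -0.92 ± 0.17 (adjusted p = 0.033, below the CD median in 26 of 27 libraries), and 1275 genes had an unadjusted p under 0.05. DESeq2 called 111 genes and limma with quality weights 56, while edgeR with the label digit as a factor called 0. Leaving out each library in turn gave 0 to 24 calls, and NCOA3 passed in 31 of 47 refits. The Th17 cytokines IL17A and IL22 had 2.26 ± 0.69 and 2.64 ± 0.81 and KLRB1, a lectin-like receptor of Th17 cells, 0.71 ± 0.21, and Th17 genes were higher for 5 of 15 adjusted over the list alone and for 0 over all genes. Immediate early genes were higher for 9 of 24 adjusted over the list alone and for 0 over all genes, JUN at 1.40 ± 0.38 and DUSP1 at 1.29 ± 0.33 (camera, adjusted p = 0.00020, and adjusted p = 0.35 with an estimated correlation). TGFBR2, a TGF-β receptor, had -0.76 ± 0.16 (adjusted p = 0.074), FOXP3 0.62 ± 0.33 and CTLA4 0.71 ± 0.30. Of markers of other cells, B and plasma cell genes had a median of 1.68 (0 of 14 higher, 6 adjusted over the list alone; fry, adjusted p = 0.031). Camera called 19 lists with the preset correlation and none with an estimated correlation (lowest adjusted p = 0.079).

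In the other fractions no gene passed with edgeR. The biopsy libraries labelled Treg (8 UC against 12 CD), in which FOXP3 had a median of 5.28 CPM against 25.1 CPM in Tmem and 19 of 20 myeloid markers were higher, had 296 genes with an unadjusted p under 0.05 of 14624 (DESeq2 2, limma 1), with RGS2, a regulator of G protein signalling, at 1.10 ± 0.29, the interferon-induced IFI6 at 1.74 ± 0.44 and FOXP3 at 1.13 ± 1.40. Blood Tmem (14 against 17) had 532 of 13805 (DESeq2 0, limma 0) and blood Treg (7 against 12) 578 of 14814 (DESeq2 0, limma 0). Each of these counts of unadjusted p lies below the share of 0.05 expected where no gene differs. The immediate early genes KLF6 and JUN had 1.04 ± 0.29 and 0.92 ± 0.27 in blood Tmem and 1.24 ± 0.27 and 1.54 ± 0.39 in blood Treg, and ITGB7 had 0.67 ± 0.28 in blood Treg. Immediate early genes were higher for 0 of 24 over all genes and 2 adjusted over the list alone in each (camera, adjusted p = 1.1e-08 and 0.00040, and adjusted p = 0.72 and 0.92 with an estimated correlation). In the libraries after treatment KLF6 and JUN were on the other side of 0, at -0.29 and -0.48 in Tmem and at -0.19 and -0.84 in Treg.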

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

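The tests of exchanged labels and of libraries that stand apart were chosen only after the result was seen. The contrast of Treg with Tmem differed between biopsies and blood for 3549 genes, by a test of the difference itself (edgeR). On the log2 scale it was higher in biopsies for C1QB (8.14), FOLR2 (7.55) and CD74 (3.22), which macrophages express, and for the collagen gene COL3A1 (8.74). It was lower for the Treg genes RTKN2 (-4.59), IKZF2 (-4.20), LAYN (-4.15), FOXP3 (-3.98), CTLA4 (-2.48) and IL2RA (-2.12), for the T cell genes TRAC (-2.14) and CD2 (-2.06) and for the mast cell gene CPA3 (-3.82), which turned to 1.20 with limma and quality weights.

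In the biopsy libraries labelled Treg, macrophage transcripts were high and T cell transcripts low, with 19 of 20 myeloid markers higher and C1QA at a median of 2425 CPM against 15.5 CPM in biopsy Tmem. These values show macrophage transcripts in the fraction, though a sort by T cell markers would be expected to remove RNA of myeloid cells. Whether such RNA also accounts for the low T cell transcripts stays open. Over the 20 libraries, within disease, the mean of 11 T cell markers had r = -0.221 with that of the myeloid markers (permutation p = 0.37, rho = -0.060 with p = 0.81, 1 relation computed, r = 0.045 without the 2 libraries farthest from the median). This relation asks only whether the amounts vary together among these libraries, and cannot decide whether all of them hold myeloid RNA. An exchange of the Treg and Tmem labels would leave the macrophage transcripts unexplained, and whether it took place was not decided. FOXP3 had a median of 5.28 CPM under the Treg label and 25.1 CPM under the Tmem label, but less T cell RNA would also lower it. The difference of the medians per library of FOXP3 per 100 CPM of T cell transcripts was -0.260, with a bootstrap interval of -2.30 to 2.09. Whether few Treg stood among the T cells of the fraction stays open: FOXP3 per T cell transcript was 1.92 times that of biopsy Tmem, with a bootstrap interval of 0.799 to 3.71 that holds 1. The pooled level per 100 CPM of T cell transcripts was 4.84 in biopsy Treg and 2.52 in biopsy Tmem, against 4.36 and 0.522 in blood, while the median per library was 1.44 and 1.70 in biopsies and 2.43 and 0.478 in blood, and a biological difference between mucosal and blood Treg was not tested apart from these.

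The 13 mitochondrially encoded genes had median log2 fold changes after vedolizumab of 0.99 in blood Tmem and 1.90 in blood Treg. Over all genes edgeR called 0 and 1 of them and DESeq2 8 and 13, and 13 passed in each with edgeR adjusted over the list alone. Neither fry nor camera with an estimated correlation called the list. The medians were 1.32 and 2.67 in CD alone and 0.46 (median SE 0.39) and 1.18 (0.59) in UC alone, where none passed adjusted over the list alone. The label digit is argued against as the whole cause in Tmem, where the median was 0.83 (median SE 0.29) with the digit as a factor, and stays open in Treg, at 1.35 (0.54). Lower depth stays open in both, since with log10 depth as a covariate the medians of 0.60 (0.28) and 1.12 (0.52) lay within 1 SE of the bound fixed for it. A few libraries that stand apart are a candidate explanation: with weights that count libraries of wide spread less, the medians fell to 0.17 (0.18) and 0.24 (0.27). An effect of the treatment was not tested apart from these and stays open.

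The chemokine genes CCL2, CCL7 and CXCL10 and the retinol dehydrogenase gene DHRS9 were lower in blood Treg after vedolizumab, with a median of -5.20. With log10 depth as a covariate the median was -5.95 (median SE 1.64), so a linear term for depth did not remove the fall. The genes had been chosen from the fit without depth, so this cannot exclude lower depth, which stays open. The calls of all 4 genes ended with the covariate while their errors widened. CCL2 went from -5.28 ± 1.13 to -4.27 ± 1.59 and CCL7 from -9.28 ± 1.51 to -8.59 ± 1.93. CXCL10 went from -5.13 ± 1.12 to -5.01 ± 1.43, and only DHRS9 moved away from 0, from -5.09 ± 1.14 to -6.88 ± 1.70. Less myeloid RNA after treatment stays open as a cause of the fall. The mean of the 4 genes followed that of 15 myeloid markers over 43 libraries within disease and time (r = 0.696, rho = 0.689, permutation p = 1e-05 for each, the smallest the permutations can give, 1 relation computed, r = 0.668 without the 2 libraries farthest from the median). This relation lies within each time, so it cannot decide what caused the fall between times. CCL7 and CXCL10 had been picked after their values were seen. The myeloid markers themselves had a median of -1.96 and 0 of 15 passed, and an effect of treatment on Treg was not tested apart from these.

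The change after treatment differed between Treg and Tmem for 194 genes by the test of the difference with edgeR, among them ELF3 (7.41) and COL3A1 (6.29), against 5 genes with DESeq2 and 0 with limma and quality weights. With the filter on libraries ELF3 stood at -2.02. In a test for single libraries far from their group, 2 of 24 ratios of the gap to the range lay above the critical value, and chance gives about 1 in 20. They were the lowest value of IL2RA (0.776) and of CCR7 (0.817) in UC blood Treg before treatment.

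Other splits of the same libraries into arms of the same sizes were fitted for each comparison. Chance can be excluded as the source of the 6891 genes between Treg and Tmem in biopsies (1 of 100 splits as large, the real one included, highest other 120), and of the 4982 and 7196 between biopsy and blood in Tmem and Treg (1 of 100 each, highest other 26 and 82). The 3549 of the difference by tissue were reached by 1 of 60 splits, the real one included (highest other 828). These splits exchanged the cell labels within disease and tissue, which removes the Treg contrast in both tissues. They cannot decide whether chance gave the difference between the tissues. For the 14 genes between Treg and Tmem in blood and the 28 in Treg after treatment 2 of 100 splits gave as many, and the highest other counts were 192 and 35. A split that called 192 genes, several times 14, points to a structure of the samples, and what it is was not tested.

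Chance cannot be excluded for the 194 genes of the difference in the change after treatment between cell types, where 30 of 60 splits gave as many and the highest gave 1384, which points to a structure of the samples or to false calls of this term, and these were not tested apart. Nor can it be excluded for the 1 gene between UC and CD in biopsy Tmem (18 of 100, highest other 2). In the comparisons with 0 calls the splits decide nothing, since any split gives at least as many (100 of 100). The highest counts there were 45 for Tmem after against before treatment, 1, 4 and 2 for UC against CD in biopsy Treg, blood Tmem and blood Treg, and 21 and 150 for the difference between diseases of the change in Tmem and Treg.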

How the results depend on the processing

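The filter on detected genes and mitochondrial share, and the list tests run with it, were chosen only after the result was seen, and the other alternatives were fixed before. No paired analysis was possible because the labels name no donors. Of 2096 values of named genes recomputed under the alternatives, 1860 kept their direction and their side of the threshold, 150 lost and 64 gained a call, and 22 turned sign, while 63 values had no test. RLE scaling left 211 of 215 such values as they were, log10 depth as a covariate 199, the label digit 187 and DESeq2 179 of 196. Leaving out the shallowest library left 24 of 24. RLE scaling moved the count of called genes by over 1.5 times in 1 comparison, and the filter on libraries in 3. Where a result changed below, the cause was not tested, except that the fits of a single disease hold fewer libraries and the fits without a filter on low counts test more genes. In data simulated from the sizes, means and dispersions of the blood Treg libraries, 3 of 100 genes changed 2-fold were recovered between after and before treatment, so changes of that size were mostly not detectable there.

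With DESeq2 the called genes were 23 in place of 14 for blood Treg against Tmem, 23 in place of 0 for Tmem after against before treatment and 163 in place of 28 for Treg. The difference of that change between the cell types had 5 in place of 194, and its difference between diseases in Treg 2 in place of 0. UC against CD had 111 in place of 1 in biopsy Tmem and 2 in place of 0 in biopsy Treg. IL2RA in biopsies turned to 0.01 and ITGA4 in Treg after treatment to 0.22. With limma and quality weights the counts were 49 for blood Treg against Tmem, 7614 in place of 4982 and 10965 in place of 7196 for biopsy against blood in Tmem and Treg, and 5 for Treg after treatment. The difference of the Treg contrast between biopsies and blood had 6918 in place of 3549, that of the change after treatment 0, and UC against CD 56 in biopsy Tmem and 1 in biopsy Treg. CPA3 in the difference between biopsies and blood turned to 1.20.

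With RLE scaling 82 genes were called in Treg after treatment, IL2RA in biopsies stood at 0.01 and ITGA4 in Treg after treatment at 0.22. With log10 depth as a covariate Treg after treatment had 0 calls and its difference from Tmem 115, and ITGA4 and ITGB7 in Treg after treatment stood at 0.04 and 0.33. With the label digit as a factor the counts were 1 and 15, UC against CD in biopsy Tmem had 0, and ITGA4 in Treg after treatment stood at 0.03. With the added filter Treg after treatment had 1 call (35 of 43 libraries left), the difference from Tmem 27 (90 of 105) and UC against CD in biopsy Tmem 5 (45 of 47). IL2RA in biopsies then stood at 0.10, ELF3 in the difference between cell types at -2.02 and ITGB7 in Treg after treatment at 0.18.

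Without a filter on low counts the calls were 13777 in place of 6891 for Treg against Tmem in biopsies, 3814 in blood, 9714 and 15130 for biopsy against blood in Tmem and Treg, and 4293 and 11492 for after against before treatment in Tmem and Treg. UC against CD then had 6794 in biopsy Tmem and 4109 in blood Tmem. The interaction terms had 6175 for tissue, 4063 for the change between cell types, and 6750 and 757 for the change between diseases in Tmem and Treg, and ITGA4 in Treg after treatment stood at 0. In 1 fit of all libraries the calls were 259 for blood Treg against Tmem, 1073 and 2909 for after against before treatment in Tmem and Treg, and 723 for their difference. The difference between diseases in that change had 1875 in Tmem and 425 in Treg. UC against CD had 892, 13, 346 and 2 in biopsy Tmem, biopsy Treg, blood Tmem and blood Treg, and IL2RA in biopsies stood at 0.02.

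In CD alone the calls were 2095 for Treg against Tmem in biopsies and 0 in blood, 2022 and 2865 for biopsy against blood in Tmem and Treg, 5 for Treg after treatment, and 420 and 0 for the differences by tissue and by cell type. ITGA4 in Treg after treatment stood at 0.41. In UC alone they were 4298 and 0, 2266 and 3416, 0 for Treg after treatment, and 878 and 0. There IL2RA and ITGAE in Treg against Tmem of biopsies stood at 0.32 and 0.12, CTLA4 in biopsy against blood Treg at 0.45 and ITGB7 in Tmem after treatment at -0.10. In the libraries after treatment blood Treg against Tmem had 8 calls, and KLF6 and JUN in UC against CD stood at -0.29 and -0.48 in Tmem and at -0.19 and -0.84 in Treg.

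With a correlation estimated for each list, camera called 0 in place of 18 lists for Treg against Tmem in biopsies, 1 in place of 12 in blood, 5 in place of 19 and 0 in place of 16 for biopsy against blood in Tmem and Treg, and 1 in place of 8 and 0 in place of 1 for after against before treatment. UC against CD had 0 in each arm in place of 19, 6, 1 and 3. The difference by tissue had 2 in place of 16 and the differences between diseases 0 in place of 3 and 0 in place of 5. With the added filter on libraries camera called 8 lists in Treg after treatment, 1 for its difference from Tmem and 0 for its difference between diseases.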

Other observations

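The overlaps of calls between diseases and between cell types were chosen only after the result was seen. Some metabolic genes were called between biopsies and blood in Tmem and in the libraries labelled Treg, which also held macrophage transcripts. PKM and ENO1, which encode the glycolytic enzymes pyruvate kinase and enolase, were higher in biopsy Tmem by 1.37 ± 0.13 and 0.94 ± 0.11 (log2, SE, edgeR, 47 against 31 libraries). In the libraries labelled Treg they were higher by 1.21 ± 0.15 and 0.81 ± 0.13 (20 against 19 libraries). SLC2A3, a glucose transporter, had -1.65 ± 0.20 and -1.55 ± 0.22 and LDHA, lactate dehydrogenase A, -0.99 ± 0.17 and -0.85 ± 0.18. Of 25 glycolysis and hypoxia genes 7 were higher and 4 lower in Tmem (7 and 4 adjusted over the list alone) and 10 higher and 5 lower in Treg (12 and 5 adjusted over the list alone). The list went both ways and was not called by camera, and its adjusted p was 0.89 and 0.66 with an estimated correlation. INSIG1, a regulator of sterol synthesis, was higher by 0.91 ± 0.18 and 2.39 ± 0.38. TXNIP, an inhibitor of glucose uptake and a target of glucocorticoids, had -1.84 ± 0.18 and -1.88 ± 0.29.

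Interferon genes divided. IRF7, an interferon regulatory factor, was higher in biopsies by 1.14 ± 0.18 in Tmem and by 1.43 ± 0.21 in Treg. The interferon-induced HERC5 and IFIT1 had -1.99 ± 0.24 and -2.64 ± 0.46 in Tmem, and IFI27 was higher by 6.53 ± 0.80 in Treg. Of 34 genes of the response 9 were higher and 6 lower in Tmem (9 and 7 adjusted over the list alone) and 13 higher and 2 lower in Treg (14 and 3 adjusted over the list alone; camera, adjusted p = 0.045, and adjusted p = 0.58 with an estimated correlation). CXCL13, a chemokine that draws B cells into follicles, was higher in biopsies by 8.54 ± 1.15 in Tmem and 5.98 ± 1.32 in Treg, in a Tfh list with 4 of 12 and 3 of 11 higher (4 and 3 adjusted over the list alone). Epithelial and stromal markers and the macrophage gene C1QC were also higher in biopsy libraries of both labels, and these genes are not specific to T cells.

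CD and UC libraries, fitted apart, called many genes in common. Between biopsy and blood Tmem 533 genes were higher and 637 lower in both diseases, where independent lists would share 61.7 and 82.7. In Treg 1235 were higher and 633 lower in both, where independent lists would share 244 and 107. Between Treg and Tmem of biopsies 1240 were higher and 357 lower in both, where independent lists would share 234 and 63.0. No gene was called in opposite directions in the diseases in these 3 contrasts. Of the genes called in Treg after vedolizumab and tested in Tmem, 12 of 13 higher and 7 of 8 lower genes had the same sign there. In Tmem edgeR called 0 genes, 1070 had an unadjusted p under 0.05 and DESeq2 called 23. The share of same signs over all genes was not computed, and with log10 depth as a covariate the 28 Treg calls became 0. The shared signs therefore cannot be assigned to treatment.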
